A study of Mus musculus with 12 samples.

How the data were processed

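Poly(A) RNA of frontal cortex was sequenced from 12 mice at 9 months of age, 6 carrying the APP/PS1 transgenes and 6 carrying them without a functional Hras gene (APP/PS1/Hras−/−). Each genotype held 3 males and 3 females. The replicate numbers follow the order of the deposited samples and do not pair mice.

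The deposited table holds counts of reads or read pairs per gene and library, without normalization. Per the labels, libraries were made with the TruSeq Stranded mRNA kit and read in pairs on an Illumina instrument. The submitters' processing notes name Trimmomatic 0.33, FastQC 0.11.7, HISAT2 2.1.0 and featureCounts. They name the builds mm10 and mm9 without saying what each was used for. The annotation release, the strand setting of the counting and the treatment of reads with several alignments are not given in the sources used here, so counts of overlapping or near-identical genes carry that uncertainty.

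Ensembl gene identifiers were matched to GENCODE M21, which gave symbols, biotypes and coordinates on GRCm38. Of 54532 genes in the table, 37 had no match, and these held 0.0099% of the counts. A count was present for 31149 genes. The filterByExpr rule of edgeR over the 4 groups of genotype and sex kept 17307 genes for testing. Total counts per library ran from 13984692 to 20174131. Levels are given as CPM, counts scaled to the library total with TMM factors. CPM means are given with the SD between mice.

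Genotype and sex effects were tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16, with robust dispersions and a Benjamini-Hochberg adjusted p threshold of 0.05. The effect across sexes and the sex effect came from an additive model of sex and genotype. The effects within males and within females and their difference (the genotype by sex interaction) came from a model of the 4 group means over all 12 libraries. Standard errors of log2 differences were derived from the F statistic, and 95% intervals from the normal quantile 1.96. Hras, App, Prnp and the RNA integrity number (RIN) of the labels were also compared with two-sided exact permutation tests. Called genes near Hras were counted within 10 Mb with a two-sided Fisher's exact test, Hras itself left out.

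The comparisons, tests and 40 gene lists, among them markers of cell types and neighbouring brain regions, were chosen before the data were examined. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists. The same test with a correlation estimated from the data and the self-contained fry test stand beside it. A camera call sets a list against the other genes, and fry asks whether its genes move on balance in 1 direction. Members of each list were also adjusted over the list alone. For each comparison the text describes the 5 called lists with the smallest p, or fewer where fewer were called.

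Named genes followed a rule chosen before the data were examined. It took Hras, App and Prnp, the called genes with the largest rises and falls and a mean of at least 1 CPM, called genes within 10 Mb of Hras, and up to 2 members with the smallest p of each described list in which no member passed. For the effect across sexes, and for each sex and the interaction, fewer than 5 genes passed, so the rule took the 5 (across sexes) or 2 rises and falls with the smallest p, given as values. Some genes that the rule took are not reported here. Genes named outside the rule are said to be chosen after their values were seen.

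Alternatives covered RLE and upper quartile scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 1 CPM in 3 libraries, non-robust dispersions, a threshold of 0.1, RIN as a covariate, other sex terms, 1 surrogate variable from sva 3.50.0, fits of 1 sex alone, omission of the X and Y chromosomes, other windows around Hras, and each library left out in turn. Omission of 2 libraries that stood apart on the first principal component, removal of per-library trends in GC content and exon length, and list tests of the sex effect were added after seeing the data. Other splits of the mice were drawn with a fixed seed. Pseudogene sequences were aligned to transcripts with blastn 2.17.0.

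The tests were checked on simulated data, in which 200 genes with a mean of at least 1 CPM were changed, 50 at each size. Counts were drawn independently for each gene, without differences in tissue content shared by many genes, so the shares may differ in the real data. Across sexes the test recovered 16% of genes changed by 0.3 on the log2 scale, 70% at 0.58, 88% at 1 and 100% at 2. The corresponding shares were 2%, 30%, 76% and 98% in males, 6%, 42%, 80% and 98% in females, and 0%, 8%, 44% and 80% for the interaction. Intervals and tests cover the mice sampled. The files hold no exon counts and no alignments, so transcript structure and sequence variants could not be examined.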

Results

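Gene expression was measured by mRNA sequencing in the frontal cortex of APP/PS1 mice, a transgenic amyloid model, and of APP/PS1 mice knocked out for Hras. Hras encodes a small GTPase of the Ras family. The 4 groups of APP/PS1 males, APP/PS1 females, APP/PS1/Hras−/− males and APP/PS1/Hras−/− females held 3 mice each. Total counts ran from 13984692 in APP/PS1/Hras−/− female 2 to 20174131 in APP/PS1 female 3. RIN was 8.32 ± 0.29 (SD, n = 6) in APP/PS1 and 8.53 ± 0.16 (SD, n = 6) in APP/PS1/Hras−/− mice (exact permutation p = 0.182). In males it was 8.1 ± 0.26 against 8.67 ± 0.058 (SD, n = 3 each), with every knockout library above every APP/PS1 library (exact permutation p = 0.1, the smallest that 3 against 3 can give). In females it was 8.53 ± 0.058 against 8.4 ± 0.1 (SD, n = 3 each, exact permutation p = 0.3).

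The libraries differed in tissue content within groups. Ttr, a transcript abundant in choroid plexus, ranged from 3.55 CPM in APP/PS1/Hras−/− female 3 to 2840 CPM in APP/PS1 female 2. Ppp1r1b, abundant in striatum, ranged from 57.1 to 201 CPM, both ends in APP/PS1 males. The first principal component held 23.9% of the variance and set APP/PS1 female 2 (score 46.8) and APP/PS1/Hras−/− male 1 (score 39.5) apart from the others. Trh stood at 17.7 and 15.6 CPM in this pair and at 10.9 CPM in APP/PS1 female 1, against at most 2.08 CPM elsewhere. Ttr, Ppp1r1b and Trh were picked for this description after their values were seen.

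The first comparison asked how loss of Hras changed the cortical transcriptome across both sexes. Only 3 of 17307 genes passed the test, and all 3 lay close together on chromosome 7. Hras (ENSMUSG00000025499, GRCm38 chromosome 7, 141189105 to 141194005, minus strand) fell by 1.95 on the log2 scale (SE 0.077, adjusted p = 3.05e-09), from 82.8 ± 9.84 to 21.3 ± 1.68 CPM (SD, n = 6 each). Hras reads thus remained at 25.8% of the APP/PS1 level. Gm5905 (ENSMUSG00000110275, 141177885 to 141178464, minus strand), a processed pseudogene 10.6 kb from Hras, rose by 6.69 (SE 0.17, adjusted p = 1.41e-11), from 0.513 ± 0.223 to 54.9 ± 5.82 CPM (SD, n = 6 each). Lrrc56 (ENSMUSG00000038637, 141194157 to 141210055, plus strand), a protein-coding gene that starts 152 bp from Hras on the opposite strand, rose by 0.91 (SE 0.099, adjusted p = 0.00128), from 5.30 ± 0.409 to 9.99 ± 1.03 CPM (SD, n = 6 each). Hras was lower, and Gm5905 and Lrrc56 higher, in each of the 6 knockout libraries than in any APP/PS1 library (exact permutation p = 0.0022 for each gene, the smallest that 6 against 6 can give).

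**Figure D1:**
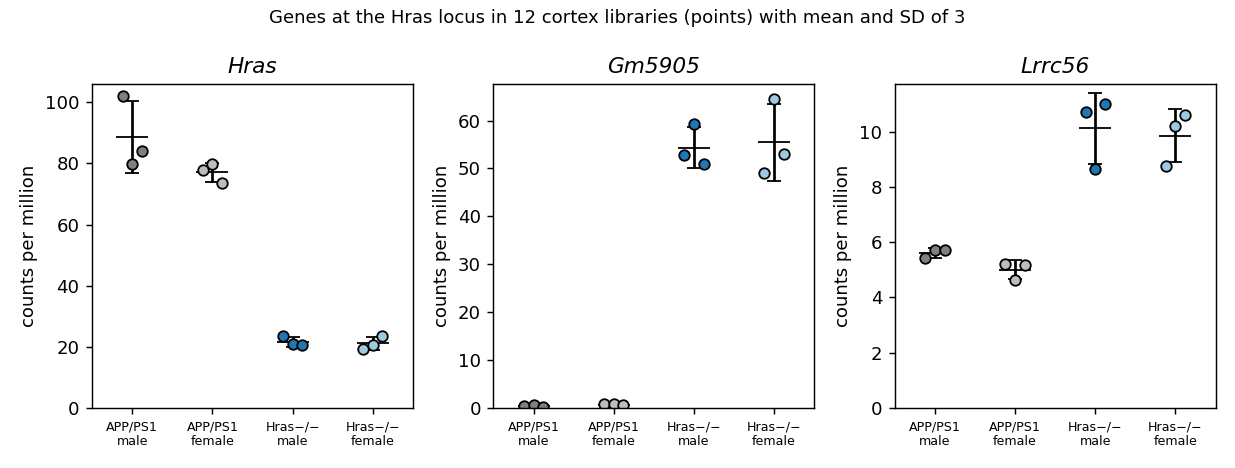
CPM of Hras, Gm5905 and Lrrc56 in each of the 12 libraries (points), with the mean and SD of the 3 mice of each group (bars); Hras−/− stands for APP/PS1/Hras−/−. Hras lay at 73.7 to 101.7 CPM in APP/PS1 and at 19.4 to 23.4 CPM in knockout libraries, and the 3 genes each separated the genotypes in both sexes.

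Within 10 Mb of Hras, 2 of the other 148 tested genes were called, against 0 of 17158 elsewhere (Fisher's exact test, p = 7.27e-05). Across all genes, 291 lay at an unadjusted p under 0.05, where 865 would be expected if p were uniform. Other splits of the mice, with 3 of each sex on a side, gave 174 to 2545 such genes, so 865 is not a firm reference here. DESeq2 called 7 genes and edgeR without a filter on low counts called 5, each including these 3. The strand setting of the counting is unknown, so the table does not show whether counts of Gm5905 and Lrrc56 came from the annotated strand.

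The genes next in rank lay on chromosome 6 and did not pass in edgeR. Gapdh, a glycolytic enzyme often used as a reference gene, had a log2 difference of −0.51 (SE 0.088, adjusted p = 0.197), with means of 54.5 and 38.4 CPM. Mbd4, a DNA glycosylase, differed by −0.52 (SE 0.11), Mrpl35, a mitochondrial ribosomal protein, by −0.51 (SE 0.12), and 0610040F04Rik by −1.04 (SE 0.27). Among higher values, Anxa4 differed by 1.07 (SE 0.22) and Smim10l1 by 0.22 (SE 0.051). DESeq2 called Gapdh (adjusted p = 0.000693) and Anxa4 (adjusted p = 0.00206). Gapdh was also called by edgeR without a filter (adjusted p = 0.00897) and without APP/PS1/Hras−/− female 1 (adjusted p = 0.00978).

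**Figure D2:**
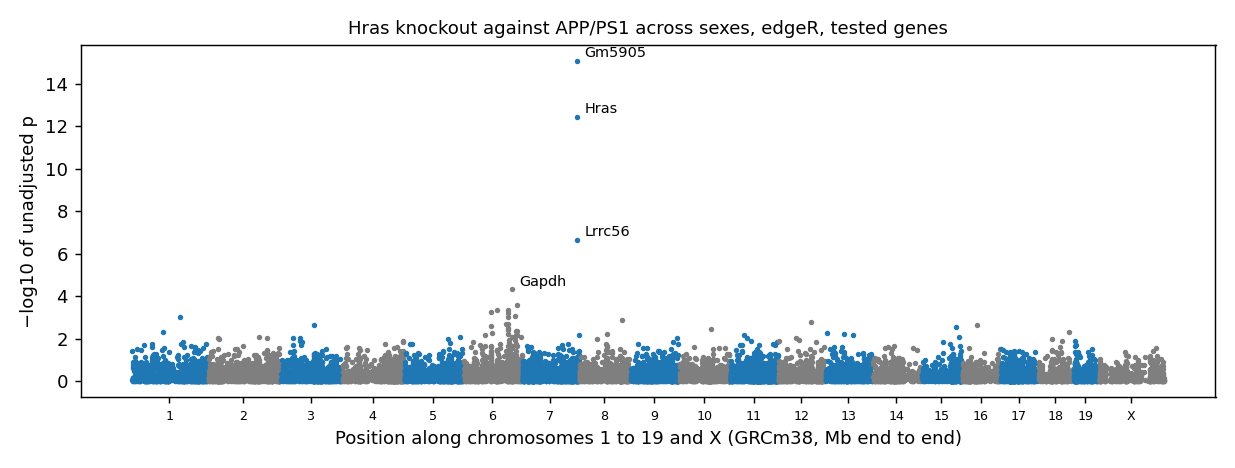
The negative log10 of the unadjusted p of each tested gene (points) for the genotype effect across sexes in edgeR, along chromosomes 1 to 19 and X in GRCm38, with colours alternating by chromosome. Gm5905, Hras and Lrrc56 on chromosome 7 were called, and Gapdh on chromosome 6 was next, with an adjusted p of 0.197.

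App and Prnp did not differ detectably. Counts of App, and of Prnp, whose promoter drives transgenes in lines of this kind, could hold reads of both the endogenous gene and a transgene, which the table does not separate. App stood at 3304 ± 344 CPM in APP/PS1 and 3524 ± 326 CPM in knockout mice (SD, n = 6 each, exact permutation p = 0.277), a log2 difference of 0.09 with a 95% interval of −0.0589 to 0.245. Prnp stood at 2311 ± 124 and 2251 ± 203 CPM (SD, n = 6 each, exact permutation p = 0.507).

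Among the 40 lists, 5 passed across sexes with the preset correlation, each with a small mean shift. Of the genes of disease-associated and plaque-induced microglia, 38 of 43 lay lower in knockout mice, with a mean log2 difference of −0.15 (adjusted p = 0.000998), and p was 0.331 with an estimated correlation. The call ended when any of 4 libraries was left out, furthest without APP/PS1/Hras−/− female 3 (mean −0.0635, adjusted p = 0.36). Their lowest p belonged to Ccl3 (−0.62, SE 0.31) and Apoe (−0.13, SE 0.082), and neither passed. Of striatal genes, 22 of 24 lay lower (mean −0.21, adjusted p = 0.0239, p = 0.42 with an estimated correlation), among them Pdyn (−0.31, SE 0.10) and Ppp1r1b (−0.32, SE 0.31), and the striatal score of single libraries ranged from −0.79 to 0.93 within APP/PS1 males alone. Of cholesterol synthesis genes, 21 of 25 lay lower (mean −0.06, adjusted p = 0.0239, p = 0.181 with an estimated correlation), among them Nsdhl (−0.13, SE 0.081). Of nuclear-encoded oxidative phosphorylation genes, 45 of 66 lay lower (mean −0.03, adjusted p = 0.0499, p = 0.473 with an estimated correlation), among them Cox8a (−0.17, SE 0.077) and Ndufb5 (−0.11, SE 0.058). Of immediate early genes, which respond to neuronal activity, 32 of 37 lay higher (mean 0.10, adjusted p = 0.0386, p = 0.395 with an estimated correlation), among them Klf4 (0.27, SE 0.14) and Fosl2 (0.22, SE 0.17).

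No list passed with an estimated correlation (lowest adjusted p = 0.903) or in fry. The transcriptional output of the MAPK pathway, downstream of Ras, did not pass (mean 0.01 over 22 genes, adjusted p = 0.355), nor did Ras proteins and their regulators (mean 0.01 over 60 genes, adjusted p = 0.288), glutamate receptors and postsynaptic proteins (adjusted p = 0.426) or amyloid precursor processing and clearance (adjusted p = 0.848). Over all lists, 1 member was called over all genes and 1 when adjusted over the list alone, which was Lrrc56 both times. The oxidative phosphorylation mean changed sign to 0.0241 with RIN as a covariate and the list was then called higher (adjusted p = 0.0473), while it lost its call once trends in GC content and length were removed (adjusted p = 0.714). With RIN the cholesterol synthesis call ended (adjusted p = 0.0575). The disease-associated microglia (mean −0.246), striatal (−0.363) and immediate early (0.196) calls held, with larger shifts. Without APP/PS1 female 2 and APP/PS1/Hras−/− male 1, the cholesterol synthesis (adjusted p = 0.139), immediate early (adjusted p = 0.268) and oxidative phosphorylation (adjusted p = 0.181) calls ended. With 1 library left out at a time, the striatal call ended for 7 of 12 libraries (mean −0.0348 without APP/PS1 male 3), the cholesterol synthesis call for 7 (mean −0.0216 without APP/PS1/Hras−/− female 2), the immediate early call for 6 (mean 0.0188 without APP/PS1/Hras−/− female 1) and the oxidative phosphorylation call for 6 (mean −0.00452 without APP/PS1 male 1).

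The second comparison took the males alone. Gm5905 rose by 7.09 (SE 0.23, adjusted p = 2.45e-09) and Hras fell by 2.04 (SE 0.11, adjusted p = 5.13e-07), and these 2 genes were the only ones called by edgeR, with 677 at an unadjusted p under 0.05. Lrrc56 differed by 0.85 (SE 0.14, adjusted p = 0.235) and Rnaseh2c by −0.64 (SE 0.15), and neither passed. DESeq2 called 4 genes, Lrrc56 among them (adjusted p = 0.00359).

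In males, 59 of 66 nuclear-encoded oxidative phosphorylation genes lay lower in the knockout, with a mean of −0.13 (adjusted p = 3.79e-15), among them Ndufc1 (−0.30, SE 0.088) and Uqcrq (−0.29, SE 0.092), subunits of respiratory complexes. With an estimated correlation p was 0.00273 (adjusted p = 0.109), and fry called the list (adjusted p = 0.0243). RIN was higher in all 3 knockout males, and with RIN as a covariate the list's adjusted p was 0.215. That adjustment rests on RIN differences within groups, which were largest among APP/PS1 males (SD 0.26, against 0.058 to 0.1 in the other groups). Cytosolic ribosomal protein genes lay lower in 66 of 78 cases (mean −0.06, adjusted p = 0.00132, p = 0.427 with an estimated correlation), among them Rps13 (−0.19, SE 0.085) and Rpl8 (−0.23, SE 0.11). With RIN as a covariate the mean was 0.229 and the list was called higher (adjusted p = 4.14e-06), and without APP/PS1 male 1 the mean was 0.0270 and the list not called (adjusted p = 0.674), nor was it without APP/PS1/Hras−/− male 3 (adjusted p = 0.143).

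Lists of other cell types lay higher in knockout males. All 20 choroid plexus and ependyma genes did so (mean 1.14, adjusted p = 0.000183, p = 0.199 with an estimated correlation), among them Dynlrb2 (1.47, SE 0.63) and Rsph1 (0.83, SE 0.47), while Ttr ran from 9.9 to 485 CPM within the 3 knockout males. Homeostatic microglia genes lay higher in 20 of 23 cases (mean 0.18, adjusted p = 0.0118, p = 0.333 with an estimated correlation), among them Sall1 (0.22, SE 0.086) and Cd33 (0.39, SE 0.17). Endothelial and mural genes lay higher in 20 of 25 cases (mean 0.12, adjusted p = 0.0252, p = 0.341 with an estimated correlation), among them Abcb1a (0.30, SE 0.13) and Tek (0.29, SE 0.13). With RIN as a covariate the choroid plexus (adjusted p = 0.976), homeostatic microglia (adjusted p = 0.331) and endothelial (adjusted p = 0.723) calls ended. Without APP/PS1/Hras−/− male 2 the homeostatic microglia mean was 0.0555 and the list not called, the endothelial mean was 0.0267 (adjusted p = 0.742) and the choroid plexus mean was 0.708 (adjusted p = 0.0838). Without APP/PS1 male 1 or male 3 the homeostatic microglia (adjusted p = 0.322 and 0.0655) and endothelial (adjusted p = 0.122 and 0.274) calls also ended. In all, 7 lists were called in males, 5 higher and 2 lower, 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 1 by fry. Once RIN was a covariate 6 were called, 3 of them higher, and 1 of the 6 was among the 7. That 1 was the ribosomal protein list, called higher with RIN and lower without it, so none of the 7 calls held in its own direction. The balance of directions turned without APP/PS1 male 1 (7 called, 3 higher), APP/PS1 male 3 (6 called, 1 higher) and APP/PS1/Hras−/− male 2 (3 called, 0 higher), and was level without APP/PS1/Hras−/− male 1 (8 called, 4 higher) and without both libraries high on the first component (8 called, 4 higher). None of the members of the 7 lists was called over all genes, and 1 was when adjusted over the list alone (Xist, in the list of X inactivation and Y genes). Xist was near the floor in males, with 1 count in total over the APP/PS1 males and 17 over the knockout males.

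The third comparison took the females alone. Gm5905 rose by 6.41 (SE 0.22, adjusted p = 2.99e-09) and Hras fell by 1.87 (SE 0.11, adjusted p = 1.50e-06). They were the only genes called by edgeR, with 659 at an unadjusted p under 0.05. Lrrc56 differed by 0.98 (SE 0.14, adjusted p = 0.0613) and Mbd4 by −0.76 (SE 0.14, adjusted p = 0.563), and neither passed. DESeq2 called 5 genes, among them Lrrc56 (adjusted p = 0.000112) and Mbd4 (adjusted p = 0.0175), and edgeR without a filter called 4, Lrrc56 among them (adjusted p = 0.0354).

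In females, 39 of 43 genes of disease-associated and plaque-induced microglia lay lower in the knockout (mean −0.34, adjusted p = 6.14e-07, p = 0.204 with an estimated correlation). Their lowest p belonged to the chemokine Ccl6 (−0.79, SE 0.29) and the lysosomal enzyme Gusb (−0.41, SE 0.16), and neither passed. The mean level of the list per library was 0.44 ± 0.13 in APP/PS1 females and 0.10 ± 0.26 in knockout females (SD, n = 3 each, mean-centred log2 CPM). Without APP/PS1/Hras−/− female 3 the mean difference was −0.19 (adjusted p = 0.0221). Immediate early genes lay higher in 33 of 37 cases (mean 0.33, adjusted p = 9.21e-07, p = 0.114 with an estimated correlation), among them Fosl2 (0.52, SE 0.21) and Plk2 (0.19, SE 0.097), and their mean was 0.208 without APP/PS1/Hras−/− female 1 and 0.508 without APP/PS1 female 3. Oxidative phosphorylation genes lay higher in 60 of 66 cases (mean 0.07, adjusted p = 5.17e-06, p = 0.0314 and adjusted p = 0.627 with an estimated correlation), among them Atp5l (0.20, SE 0.084) and Ndufa5 (0.23, SE 0.096).

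Lists of tissue around the cortex lay lower in knockout females. Leptomeningeal and fibroblast genes did so in 19 of 20 cases (mean −0.37, adjusted p = 8.34e-05, p = 0.173 with an estimated correlation), among them Mgp (−0.57, SE 0.19) and Ogn (−0.70, SE 0.28). Mgp lies on chromosome 6, whose pattern is described below. It also lay lower in knockout males (−0.28), although the list's mean level was −0.26 in APP/PS1 males and −0.07 in knockout males. All 20 choroid plexus and ependyma genes lay lower (mean −1.08, adjusted p = 0.000125, p = 0.21 with an estimated correlation), among them Igfbp2 (−0.76, SE 0.34) and Calml4 (−2.17, SE 1.06), with Ttr at 2840 CPM in APP/PS1 female 2. Without that library alone the choroid plexus mean was 0.0236 (adjusted p = 0.942) and the leptomeningeal mean −0.161 (adjusted p = 0.0964), and without APP/PS1/Hras−/− female 3 the choroid plexus mean was −0.539 (adjusted p = 0.0533). Without APP/PS1 female 2 and APP/PS1/Hras−/− male 1 the choroid plexus mean was 0.0241 and the leptomeningeal call ended (adjusted p = 0.0823). In all, 16 lists were called in females, 5 higher and 11 lower, with 0 called by an estimated correlation (2 at an unadjusted p under 0.05) or by fry. The balance of directions turned with RIN as a covariate (19 called, 10 higher) and without APP/PS1/Hras−/− female 3 (16 called, 9 higher). None of the members of the 16 lists was called over all genes, and 1 was when adjusted over the list alone (Hba-a1, in the blood list).

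The fourth comparison asked whether the genotype effect differed between the sexes. No gene was called by edgeR, DESeq2 or limma-voom, with 1248 genes at an unadjusted p under 0.05 in edgeR. The interaction estimates were 0.17 (SE 0.15) for Hras, −0.68 (SE 0.39, adjusted p = 0.676) for Gm5905 and 0.12 (SE 0.20) for Lrrc56. The smallest p belonged to Tpm2 (0.86, SE 0.21), Rnaseh2c (0.89, SE 0.22), Pdgfra (−0.85, SE 0.19), a marker of oligodendrocyte precursors, and Pcdhb12 (−0.88, SE 0.20), all at an adjusted p of 0.667. Across the 17307 genes, which are not independent replicates, the male and female log2 differences had a Pearson correlation of −0.264 and a Spearman correlation of −0.308, and 37.3% of genes had the same sign. Over the 10440 genes with a mean of at least 10 CPM the Pearson correlation was −0.157, the Spearman correlation was −0.438 and 33.8% of genes had the same sign, so the Pearson value alone was weaker there. Over all genes the Pearson correlation was −0.0241 without APP/PS1 female 2, −0.0170 without APP/PS1/Hras−/− male 1 and 0.0382 without both.

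Oxidative phosphorylation genes gave the smallest p among interaction lists. The female difference exceeded the male difference for 65 of 66 genes (mean 0.21, adjusted p = 3.14e-15), among them the complex I subunits Ndufa8 (0.41, SE 0.12) and Ndufs6 (0.43, SE 0.13). With an estimated correlation p was 0.00268 (adjusted p = 0.107), and fry called the list (adjusted p = 0.0127). The mean level per library was 0.08 ± 0.06 in APP/PS1 males, −0.05 ± 0.03 in knockout males, −0.05 ± 0.02 in APP/PS1 females and 0.02 ± 0.01 in knockout females (SD, n = 3 each, mean-centred log2 CPM), an order opposite to that of the group means of RIN within each sex. With RIN as a covariate the mean interaction was 0.0952 and the list was still called (adjusted p = 0.0222).

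Immediate early genes had a higher female than male difference in 32 of 37 cases (mean 0.46, adjusted p = 3.65e-05, p = 0.167 with an estimated correlation), among them Gadd45g (0.63, SE 0.29) and Ier5 (0.90, SE 0.43). Homeostatic microglia genes had a lower one in 20 of 23 cases (mean −0.38, adjusted p = 5.42e-05, p = 0.186 with an estimated correlation), among them Sall1 (−0.38, SE 0.12) and Cx3cr1 (−0.47, SE 0.17), and lost the call with RIN as a covariate (adjusted p = 0.982). Choroid plexus and ependyma genes had a lower one in all 20 cases (mean −2.23, adjusted p = 1.59e-06, p = 0.129 with an estimated correlation), among them Foxj1 (−0.95, SE 0.39) and Ccdc153 (−2.04, SE 0.85), with an adjusted p of 0.431 once RIN was a covariate. Leptomeningeal and fibroblast genes had a lower one in 19 of 20 cases (mean −0.56, adjusted p = 0.000145, p = 0.188 with an estimated correlation), among them Bmp6 (−0.95, SE 0.34) and Slc13a4 (−1.17, SE 0.51), and lost the call without APP/PS1 female 2 and APP/PS1/Hras−/− male 1 (adjusted p = 0.103). These calls held with any single library left out, though the choroid plexus mean was −1.12 and the leptomeningeal mean −0.352 without APP/PS1 female 2, and the homeostatic microglia mean −0.251 without APP/PS1/Hras−/− male 2. In all, 16 lists were called, 6 higher and 10 lower, with 0 called by an estimated correlation and 1 by fry. With RIN as a covariate 17 were called, 11 higher and 6 lower, and 9 of the 17 were among the 16. The balance was level without APP/PS1 male 1 (18 called, 9 higher), APP/PS1/Hras−/− female 3 (18 called, 9 higher) or APP/PS1/Hras−/− male 2 (10 called, 5 higher). The lists called and the balance of directions thus changed with RIN and with single libraries. None of the members of the 16 lists was called over all genes, and 2 were when adjusted over the list alone (Pdgfra and Cspg4, in the list of oligodendrocyte precursors).

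**Figure D3:**
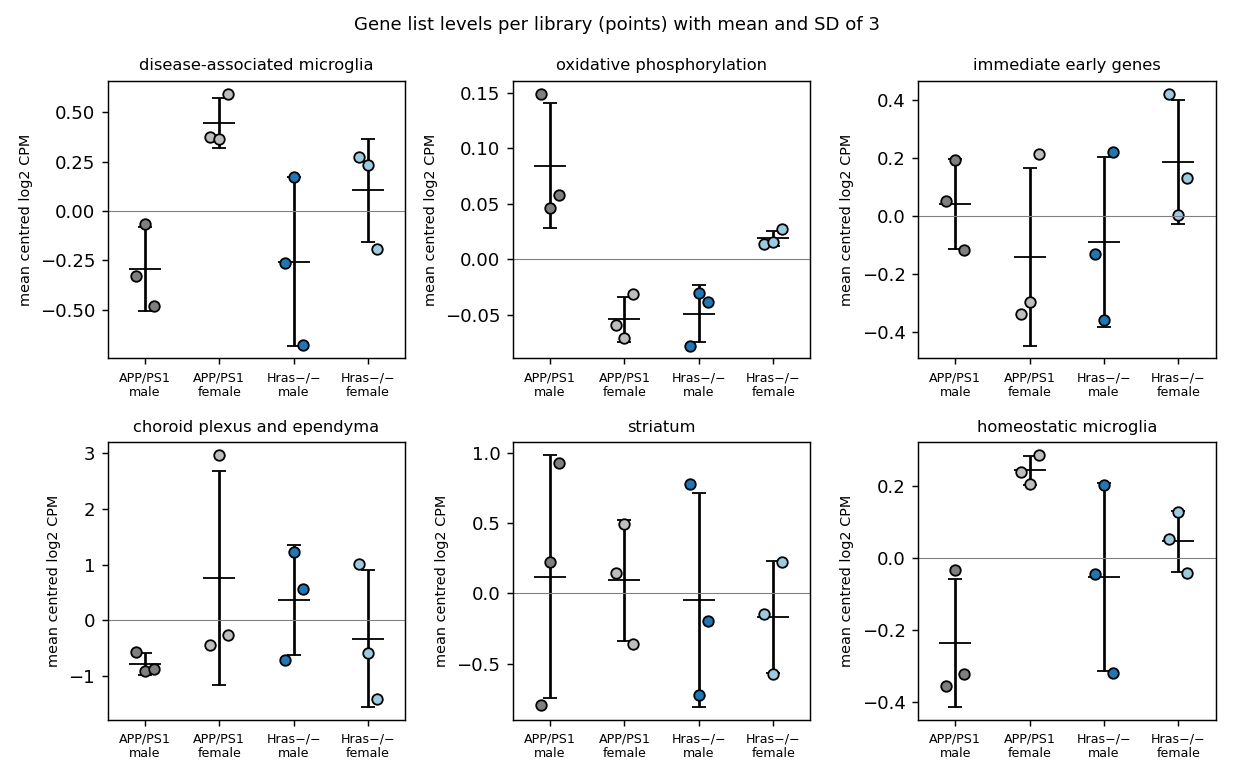
Mean-centred log2 CPM averaged over the members of 6 gene lists in each of the 12 libraries (points), with the mean and SD of the 3 mice of each group (bars); Hras−/− stands for APP/PS1/Hras−/−. The oxidative phosphorylation level was 0.08 in APP/PS1 males and −0.05 in knockout males, and the choroid plexus level of APP/PS1 female 2 stood at 2.97, above the other 11 libraries.

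The last comparison set females against males across genotypes. Xist, the RNA that silences 1 X chromosome, stood at 863 CPM in females (9833 to 18975 counts) and had 0 to 8 counts in males. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 96.8, 102, 64.6 and 26.1 CPM in males and 0 to 3 counts in each female, and the Y-linked Gm29650 had 8.56 CPM in males and 0 counts in females. All 12 libraries thus carried the sex of their label. Among genes known to escape X inactivation, Eif2s3x rose by 0.65 (SE 0.069, adjusted p = 0.000429), Ddx3x by 0.45 (SE 0.065, adjusted p = 0.00996) and Kdm5c by 0.36 (SE 0.055, adjusted p = 0.0174) in females. The 3 other called genes, named after their values were seen, lay together at the distal end of the X chromosome and were lower in females: Hccs fell by 0.91 (SE 0.069), BC022960 by 0.96 (SE 0.11) and Gm15246 by 0.98 (SE 0.16).

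In all, 12 genes were called between the sexes by edgeR, 4 higher and 8 lower in females, and 27 by DESeq2, 19 of them higher. With X and Y genes left out, 0 were called by edgeR, and 804 of all tested genes lay at an unadjusted p under 0.05. The count was 20 without APP/PS1/Hras−/− male 2, 13 of them higher, so the balance of directions was not stable. Kdm5c missed the threshold when any of 9 libraries was left out (adjusted p of up to 0.0814, without APP/PS1/Hras−/− female 1), and Ddx3x when APP/PS1 female 3 was (adjusted p = 0.0563).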

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

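The tests of RIN and of GC content and length for the oxidative phosphorylation genes, and the splits scored by their best list, were chosen after the result was seen.

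In APP/PS1 mice, Hras in APP/PS1 male 1 stood at 102 CPM, with the next library at 84 CPM. The gap was 0.632 of the group's range, above Dixon's 95% critical value for 6 samples. Over the 32 groups examined this way 1 such library was found, where chance gives 1.6.

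The genotype effect on nuclear-encoded oxidative phosphorylation genes differed between the sexes in the list test, with a mean interaction of 0.206, lower in knockout males and higher in knockout females than in APP/PS1 mice of the same sex. The call ended with an estimated correlation (adjusted p = 0.107). It was the best of 40 lists, and in 13 of 100 splits of the mice the best list had a p as small (negative log10 of p: real 16.1, highest other 26.1), so chance cannot be excluded. Removal of trends in GC content and length gave a mean of 0.239, which argues against such trends as the cause. With RIN as a covariate the mean interaction was 0.0952, 46.2% of its value, with an SD between genes of 0.19. The list was still called (adjusted p = 0.0222), and RNA quality may account for part of the pattern. The adjustment is uncertain, since it rests on RIN differences within groups, which were largest among APP/PS1 males (SD 0.26, against 0.058 to 0.1 in the other groups). RIN was higher in every knockout male than in any APP/PS1 male, so in males it goes with genotype, and a response of the sexes to loss of Hras remains open and untested.

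Other lists also differed between the sexes in the test of the interaction, and are given as values. The mean interaction was −2.23 for choroid plexus and ependyma genes, 0.458 for immediate early genes, −0.381 for homeostatic microglia genes and −0.565 for leptomeningeal and fibroblast genes. With an estimated correlation none of the 4 was called (adjusted p = 0.5684 for each). The choroid plexus (adjusted p = 0.431) and homeostatic microglia (adjusted p = 0.982) calls ended with RIN as a covariate. The immediate early (adjusted p = 0.0291) and leptomeningeal (mean −1.46, adjusted p = 3.13e-08) calls held with it. Without APP/PS1 female 2 the choroid plexus mean was −1.12.

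For the counts of called lists, chance cannot be excluded for the genotype effect across sexes, where 98 of 100 splits called as many lists (real 5, highest other 23), or for the interaction, where 18 of 100 did (real 16, highest other 23). Within a sex there are 10 splits, too few for a share under 0.05: 8 called as many lists in males (real 7, highest other 18) and 3 in females (real 16, highest other 17).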

How the results depend on the processing

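Without the 2 libraries high on the first component, and with trends in GC content and length removed, values were computed by choices added after seeing the data. Hras and Gm5905 were called across sexes and in each sex under every alternative, as was Lrrc56 across sexes. Leaving out each library in turn gave 3 to 4 genes across sexes, 2 to 3 in males, 2 to 3 in females, 0 to 0 for the interaction and 9 to 20 for sex (20 without APP/PS1/Hras−/− male 2). It gave 1 to 8 lists across sexes (3 without APP/PS1 male 1, 1 without APP/PS1 male 2, 2 without APP/PS1 female 1, 8 without APP/PS1/Hras−/− male 1, 1 without APP/PS1/Hras−/− male 3), 3 to 13 in males (3 without APP/PS1/Hras−/− male 2, 13 without APP/PS1/Hras−/− male 3), 11 to 19 in females and 10 to 19 for the interaction (10 without APP/PS1/Hras−/− male 2), and a male to female correlation from −0.320 to −0.0170 (−0.0241 without APP/PS1 female 2, −0.0170 without APP/PS1/Hras−/− male 1). DESeq2 called 7 genes across sexes, 4 in males, 5 in females and 27 for sex. Without a filter, edgeR called 5 across sexes and 4 in females. Without X and Y genes 0 sex differences were called, since those genes had been the called ones. With an estimated correlation 0 lists were called in each of the 4 comparisons, and fry called 0 across sexes, 1 in males, 0 in females and 1 for the interaction. RIN as a covariate gave 14 lists across sexes, and omission of both libraries high on the first component gave 3. The correlation was −0.157 over genes of at least 10 CPM and 0.0382 without both libraries.

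Signs changed for some named genes, none of them called. With RIN, Prnp was 0.00174 across sexes. In males Cd33 was −0.0589, Dynlrb2 −1.53, Abcb1a −0.0878, Rps13 0.00569 and Rpl8 0.183. For the interaction Foxj1 was 0.425, Ccdc153 1.43 and Gadd45g −0.51. Among lists, with RIN, oxidative phosphorylation across sexes was 0.0241 and ribosomal proteins in males 0.229, both then called higher (−0.129 to 0.0270 with each library left out, the latter without APP/PS1 male 1), homeostatic microglia 0.0301 in males and −0.192 for the interaction, and choroid plexus in males 0.706. For choroid plexus in males, and for homeostatic microglia in males and in the interaction, the list test turned while the mean kept its sign. Choroid plexus in females was 0.0241 without both libraries. Of the other values of named genes 1618 kept direction and side of the threshold, 9 newly passed and 12 no longer passed. Of those of described lists 263 kept both and 90 no longer passed. The cause was not tested. With 13984692 to 20174131 counts per library and 3 mice per group, simulated changes of 0.58 on the log2 scale were recovered in 70% of genes across sexes and in 8% for the interaction, so smaller changes were mostly not detectable.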

Other observations

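The tests of Rps9 reads and of linked variants at the Hras locus were chosen after the result was seen, as were the list tests of the sex effect, the splits scored by their best list, those with Hras left out and the search for pseudogene parents; the chromosome 6 pattern was itself noticed in these data.

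Females showed higher levels of microglial, interferon and reactive astrocyte lists than males in the fit over both genotypes. Of disease-associated and plaque-induced microglia genes 40 of 43 lay higher in females, with a mean log2 difference of 0.55 (p = 0.0202 with an estimated correlation), and 28 passed when adjusted over the list alone. For the lists that follow, that number was 0 for interferon response, 0 for reactive astrocytes and 10 for homeostatic microglia. All 34 interferon response and antigen presentation genes lay higher (mean 0.45, p = 0.028 with an estimated correlation), as did 26 of 27 reactive astrocyte genes (mean 0.39, p = 0.014) and 22 of 23 homeostatic microglia genes (mean 0.29, p = 0.0405). With an estimated correlation the adjusted p of each of these 4 lists was 0.18, and fry called none of them (lowest adjusted p = 0.0945), so their calls rested on the preset correlation. The sexes lay closer together in the knockout for disease-associated microglia (−0.29 ± 0.21 in APP/PS1 males, 0.44 ± 0.13 in APP/PS1 females, −0.26 ± 0.43 in knockout males and 0.10 ± 0.26 in knockout females, SD, n = 3 each, mean-centred log2 CPM) and for homeostatic microglia (−0.24 ± 0.18, 0.24 ± 0.04, −0.05 ± 0.26 and 0.05 ± 0.08 in the same order). The interaction of both lists, and of reactive astrocyte genes, was called with the preset correlation (adjusted p = 0.000304, 5.42e-05 and 0.00472) and not with an estimated one. The group means of the interferon list went the other way, with sexes further apart in the knockout (−0.16 ± 0.23 in APP/PS1 males, 0.21 ± 0.18 in APP/PS1 females, −0.29 ± 0.10 in knockout males and 0.24 ± 0.44 in knockout females). Knockout females 1, 2 and 3 scored 0.714, 0.151 and −0.147, so this direction rested on APP/PS1/Hras−/− female 1 alone. Lists of other tissue also lay higher with the preset correlation: leptomeningeal and fibroblast genes in all 20 cases (mean 0.33, p = 0.127 with an estimated correlation), choroid plexus and ependyma genes in all 20 (mean 0.42, p = 0.494) and endothelial and mural genes in 23 of 25 (mean 0.16, p = 0.156), so a difference in tissue content between the sexes remains open. Not all glial lists rose, as oligodendrocyte and myelin genes had a mean of −0.08 (adjusted p = 0.0816) and astrocyte genes one of 0.07 (adjusted p = 0.0805). Single genes chosen after their values were seen included Itgax, an integrin of plaque-associated microglia, at 9.58 and 10.3 CPM in APP/PS1 and knockout males against 24.2 and 21.1 CPM in females (1.19, SE 0.23, adjusted p = 0.285), Cst7 (1.31, SE 0.35), Trem2 (0.68, SE 0.19) and the astrocyte filament gene Gfap (0.53, SE 0.16), none of which passed over all genes. In the list test with the preset correlation 17 of 40 lists were called, also without both libraries high on the first component, and 2 with an estimated correlation, both of them lists of X and Y genes. In 2 of 60 splits of sex within genotype, the real one among them, the best of the lists other than those of X and Y genes had a p as small (negative log10 of p: real 30.03, highest other 30.89). The real best list was that of disease-associated and plaque-induced microglia. That p is the one at the preset correlation, and the splits were scored this way after the result was seen, so they do not exclude chance.

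At the Hras locus, Gm5905 and Lrrc56 rose where Hras fell. Gm5905 is 97.3% identical to Rps9 over 585 bp, and it gained 54.4 CPM. Rps9 had a log2 difference of 0.0173 (SE 0.0636), where a fall by 54.4 CPM to its knockout mean of 174 CPM would give −0.392. These values argue against a full move of the gained counts from Rps9 to Gm5905. They do not cover reads left uncounted in APP/PS1 mice, since the treatment of reads with several alignments is not known. In the split described below, Atp6v0c-ps2 gained more counts than its parent Atp6v0c lost, so a parent's level is an uncertain guide. Variants of another strain linked to Hras cannot be told apart from an effect of the targeted allele, since 3 of 146 other genes within 10 Mb lay at an unadjusted p under 0.05 against 281 of 16537 elsewhere, an odds ratio of 1.21 with a 95% interval of 0.246 to 3.66. Transcription that runs from the targeted allele into its neighbours, and a response of these genes to loss of Hras, remain open and could not be tested without exon counts.

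Chromosome 6 held 56 of 867 tested genes at an unadjusted p under 0.05 for the genotype effect across sexes, 6.46% against 1.46% on the other autosomes, a ratio of 4.42, with the highest share, 26.8%, from 130 to 140 Mb. Only the real 1 of 100 splits set any autosome that far above the rest. The highest other ratio, 4.09 on chromosome 17, came from a split that followed a structure of the mice apart from genotype, described below. The splits therefore do not exclude that a structure of this kind fell unevenly between the genotypes by chance. The ratio was 4.17 with trends in GC content and length removed, which argues against these. A segment of another strain that differs between the genotypes may account for it but cannot be told apart from other causes. Of chromosome 6 genes at a small p in 1 sex, 54.3% kept their sign in the other, against 24.3% on other autosomes. Fisher's exact test, which takes linked genes as independent, gave p = 9.64e-11. The share was below the 60% the explanation was taken to need, a bar that took no account of the 37.3% of all tested genes with the same sign. No biological explanation was tested.

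For the genotype effect across sexes 3 of 100 splits called as many genes (real 3, highest other 20), but Hras, the targeted gene, was expected to be among them. With Hras left out 5 of 100 splits did (real 2, highest other 20), so the count alone does not exclude chance. The 2 genes, Gm5905 and Lrrc56, each separated all 6 knockout from all 6 APP/PS1 libraries. Within 10 Mb of Hras 2 of 148 genes were called against 0 of 17158 elsewhere (Fisher's exact test, p = 7.27e-05). Neither value is a separate test of chance, since the 2 genes were selected as called and lie beside the same targeted gene. Genes called in the split with 20 calls also separated 6 libraries from the other 6. For sex 2 of 60 splits called as many genes (real 12, highest other 20), and all 12 were X- or Y-linked. For the interaction the real count was 0, which all 100 splits reach whatever they call (100 of 100, highest other 18), so the splits say nothing about it. The 10 splits within a sex are too few for a share under 0.05 (males: 1 split, real 2, highest other 0; females: 1 split, real 2, highest other 0). A correlation between the male and female effects as low as −0.264 came from 11 of 100 splits (lowest other −0.408), so chance cannot be excluded for it.

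The split with 20 calls points to a structure of the mice apart from genotype and sex. Of its 20 genes 12 lay on chromosome 17, from 23.8 to 45.7 Mb, and the other 8 were pseudogenes or copies whose best protein-coding match lay on chromosome 17. Atp6v0c-ps2, 99.8% identical to Atp6v0c, stood at 0.997 to 1.55 CPM in APP/PS1 males 2 and 3, APP/PS1 female 2, APP/PS1/Hras−/− male 3 and APP/PS1/Hras−/− females 1 and 2, and at 71 to 101 CPM in the other 6 libraries. Rps18 stood at 115 to 133 CPM in the former and 72.4 to 81.5 CPM in the latter, and Gm11361, 99.3% identical to it, at 0.518 to 1.07 and 13.5 to 17.4 CPM. Parents did not all lose what their copies gained. Atp6v0c stood at 36.7 to 47 CPM in the former and 24 to 32.5 CPM in the latter. Glo1, the match of Gm13443, was higher in the latter, at 93.5 to 113 CPM against 62.3 to 71.8 CPM. Each genotype and each sex had 3 libraries on either side, and these values were not tested, since the sides are defined by them. The sides were not balanced for the interaction. The former held more APP/PS1 than knockout males and more knockout than APP/PS1 females. C4a, Rps18 and Rps2, members of tested lists, were among the 20 genes, so this structure can enter the comparisons within a sex and the interaction.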
